A study of Mus musculus with 7 samples.

How the data were processed

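Gene expression was compared between 3 control lines and 4 NAC lines from mouse lung tumours, 1 RNA sequencing library per line. The authors deposited raw counts per gene symbol, 1 column per line, and named STAR 2.5.0a, featureCounts 1.5.2, DESeq2 (version not stated) and the mm10 genome. The strand setting and the gene annotation are not stated. The authors also deposited a comparison table with, per the file headers, a mean signal scaled by size factors, log2 fold changes with their standard errors, a Wald score, and a p-value with its adjusted p-value, for genes under an adjusted p-value of 0.05. That table does not state its direction, which was read from the match of its signs with the deposited counts.

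Gene symbols were matched to GENCODE annotation of the same genome: of 24421 genes, 23311 matched by symbol and 666 by synonym, 41 were ambiguous, 27 had symbols turned into dates and 376 had no match. GC content and length were available for 99.1% of tested genes. Total counts were 37523346, 41461116 and 43170694 in control lines 1 to 3 and 38260805, 42249215, 42803528 and 37246817 in NAC lines 1 to 4. A gene with no count in a group was set against a floor of 3 counts over the group, and for 1 to 3 counts a 95% counting interval of the ratio is given. Floors and intervals cover counting error only.

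Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with group as the only term and 5 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 over 13027 genes counted as a change. CPM use the TMM-scaled library sizes, and log2 CPM a prior count of 2. Gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, where at least 5 members were tested, with adjustment over 25 lists; an estimated correlation and fry were run beside it. Separation of the groups was tested by an exact permutation over 35 splits on the 500 most variable genes. Chromosome medians used genes above a mean log2 CPM of 4. Sequence shared between genes was counted as the share of a gene's 50-base words that occur in transcripts of other genes.

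Genes were named by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between groups, up to 4 members with the smallest p from each list, and Bach1, Nfe2l2, Keap1, Hmox1, Hk2, Gapdh, Kras, Nnt and Trp53. Genes named outside it are said to be chosen after their values were seen.

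Alternatives fixed beforehand were RLE, upper quartile and library size scaling, no filter and a stricter filter (1 CPM in 3 lines), DESeq2 1.42.0, limma-voom, robust fitting, a block for the number in the line names (mTC11 with mTN11, mTC14 with mTN14, the other lines alone), other gene sets and prior counts for the distances, and leaving out each line. Autosomal genes alone, leaving out chromosomes X, Y and 13, a GC content and length correction, summing control lines 1 and 2, and the bias-adjusted quasi-likelihood method were added after the data were seen. On simulated counts for 13027 genes, the test recovered 10 of 100 genes changed 2-fold and 73 of 100 changed 4-fold, with 4 false calls among 87 and 0 wrong signs.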

Results

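RNA sequencing was carried out on 7 mouse cell lines established from lung tumours. The donor mice were of mixed C57BL/6-129/Sv background and carried 1 activating allele of the oncogene Kras. Control lines 1, 2 and 3 (mTC11, mTC14 and mTC31) came from control mice, and NAC lines 1, 2, 3 and 4 (mTN11, mTN12, mTN13 and mTN14) came from mice whose drinking water held N-acetylcysteine (NAC), a cysteine donor used as an antioxidant. The cells themselves received no treatment and were grown in the same medium, with 1 g/L glucose and 10% serum. The submitters describe the lines of a group as biological replicates. Whether each line came from a separate animal or tumour is not given in the labels, so the p-values below measure the spread between these lines. Total counts ran from 37246817 in NAC line 4 to 43170694 in control line 3, and 13027 genes had enough counts to be tested. Values are CPM, read counts scaled to the size of each library, as mean ± SD over 3 control and 4 NAC lines unless 1 line is named.

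The comparison asked which transcripts differ between tumour lines whose mice had received the antioxidant and lines whose mice had not. NAC lines had high Y-linked transcripts and hardly any Xist, lower Bgn, Fstl1 and Acta2, and higher Il1a, Muc4 and Ldlr. The Y-linked genes and Xist passed the test below without each line in turn. The other genes passed in fewer of the 7 fits that left out 1 line: Bgn in 5, Muc4 in 4, Fstl1 in 3, Il1a and Ldlr in 2 each and Acta2 in 1. In NAC lines 71 genes were higher and 61 were lower at an adjusted p under 0.05 (edgeR quasi-likelihood test), 132 in all. Of these, 4 lay on the Y chromosome, 7 on X and 121 on autosomes. The CPM of the groups did not overlap for any of the 132, and for 18.9% of all tested genes, where chance gives 5.71%. The lines also lay farther apart between groups than within them: the mean distance over the 500 most variable genes was 89.5 log2 units between groups and 65.8 within (one-sided exact permutation test over 35 splits, p = 0.0286, the smallest it can give; with control lines 1 and 2 taken as 1 sample, 15 splits allow none below 0.0667). Within the control group, lines 1 and 2 were 24.0 apart, the closest pair on this measure, against 82.3 and 87.9 for their distances to line 3. Over all tested genes NAC lines 1 and 3 were more alike (Spearman's rho across genes 0.986, against 0.978 for control lines 1 and 2). The number of calls rested on control lines 1 and 2: it was 6 without control line 1, 9 without control line 2 and 7 when both were summed as 1 sample. With both summed, 21 of the 26 called genes among those named lost the call. The number of calls also moved with the other lines. It was 42, 37 and 36 without NAC lines 1, 3 and 4, and 261 without control line 3. DESeq2 called 1087 genes on the same counts.

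**Figure D1:**
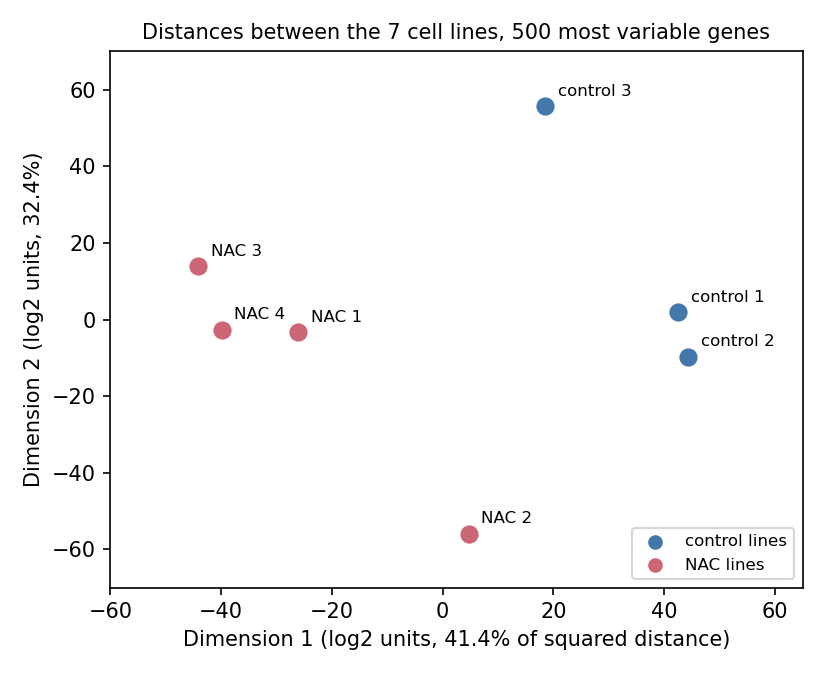
Classical scaling of the distances between the 7 lines over the 500 most variable tested genes (log2 CPM, prior count 2); both axes are in log2 units and each point is 1 line. Control lines 1 and 2 lie together, and control line 3 and NAC line 2 each lie apart from the rest of their group along the second axis.

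Sex-linked transcripts were among the largest differences in both directions. Xist, the noncoding RNA made from the inactive X chromosome of female cells, was at 184 ± 61.9 CPM in control lines and 0.238 ± 0.207 CPM in NAC lines (adjusted p = 0.00144; chromosome X, 103460366 to 103483254, mm10, minus strand). The Y-linked genes went the other way. Ddx3y, which encodes an RNA helicase, was at 0.118 ± 0.0627 CPM in control lines and 46.7 ± 9.79 CPM in NAC lines (adjusted p = 0.000261; chromosome Y, 1260771 to 1286629). Eif2s3y, encoding a translation initiation factor subunit, rose from 0.0474 ± 0.0203 to 23.9 ± 4.10 CPM (adjusted p = 0.000257), and Kdm5d, a histone demethylase, from 0.0823 ± 0.0408 to 25.6 ± 8.47 CPM (adjusted p = 0.000861). Uty had 1 count over the 3 control lines and 19.2 ± 4.26 CPM in NAC lines, a ratio of 2398 with a 95% counting interval from 430 to 94760. Every control line was thus high in Xist and every NAC line high in Y transcripts, so sex-linked expression separated the 7 lines in the same way as the treatment of the mice. No group held lines of both kinds. All 5 sex-linked genes passed the test, also when adjusted over the list alone (camera adjusted p = 4.88e-07; adjusted p = 0.170 with an estimated correlation).

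**Figure D2:**
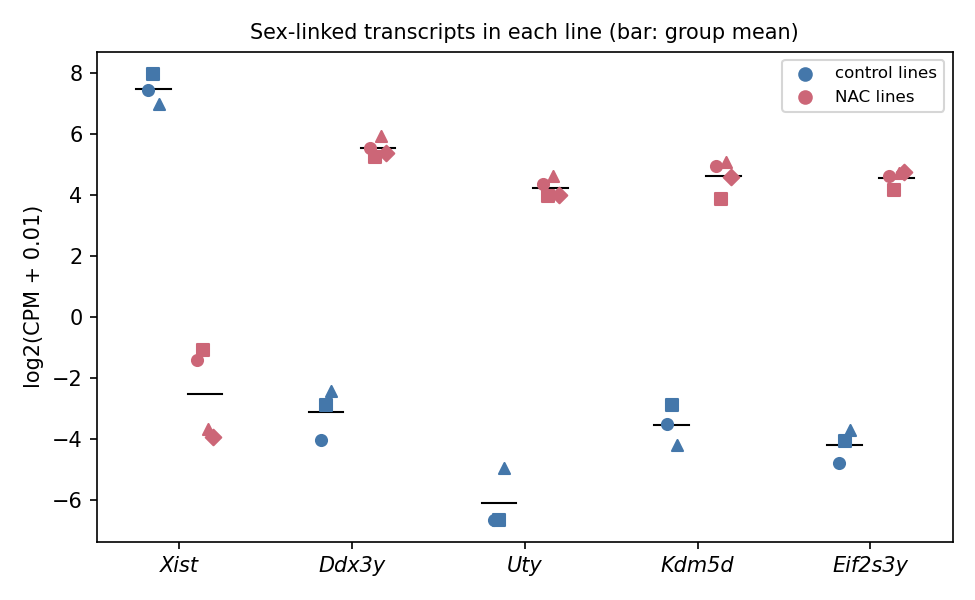
Expression of Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y in each line, as log2 of CPM plus 0.01; circles, squares, triangles and diamonds are lines 1 to 4 of a group and bars are group means. Xist is at 127 CPM or above in each control line and at 0.462 CPM or below in each NAC line.

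Outside the Y chromosome, the genes with the largest rises in NAC lines were mostly near the floor in control lines. Il1a, which encodes the inflammatory cytokine interleukin 1 alpha (chromosome 2, 129299610 to 129309972), rose from 0.0550 ± 0.0317 to 11.1 ± 9.11 CPM (log2 fold change 7.56, SE 1.16, adjusted p = 0.0321). Ly6k, a member of the Ly6 family of surface proteins, had 1 count over the control lines and 11.1 ± 8.73 CPM in NAC lines (adjusted p = 0.0392), with NAC line 2 at 0.608 CPM. Slc15a2, a peptide transporter, reached 3.48 ± 1.06 CPM from 3 control counts (ratio 142, counting interval 48.3 to 690). Muc4, a membrane mucin of epithelia, rose from 0.0317 ± 0.0108 to 2.58 ± 2.08 CPM (adjusted p = 0.0273). Zfp951, a zinc finger gene (2.73 ± 1.45 CPM), and Clec2f, of the C-type lectin family (2.20 ± 1.42 CPM), completed the 10 largest rises, with 1 and 2 control counts. In the reference transcripts, 32.7% of the Ly6k sequence occurs in another annotated gene, so its counts depend on how shared reads were assigned.

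Among the 10 largest falls, Bgn, which encodes the matrix proteoglycan biglycan (chromosome X, 73483602 to 73495933), fell from 918 ± 106 to 1.60 ± 1.69 CPM (log2 fold change -9.17, SE 1.08, adjusted p = 0.0179) and was the most abundant. Fstl1, a secreted glycoprotein, fell from 10.4 ± 5.19 to 0.0698 ± 0.0695 CPM (adjusted p = 0.0215). Acta2, smooth muscle actin, fell from 9.30 ± 12.2 to 0.0705 ± 0.0483 CPM (adjusted p = 0.0346), with 23.3 CPM in control line 3. Peg12, an imprinted gene on chromosome 7, had 3.35 ± 1.63 CPM in control lines and no count in any NAC line, at least 173-fold lower against a floor of 3 counts over the group. The protocadherin genes Pcdhga5 and Pcdhga11 on chromosome 18 fell from 4.37 ± 0.921 and 7.97 ± 1.93 CPM to 0.0248 ± 0.0200 and 0.0445 ± 0.0530 CPM; 45.3% and 72.4% of their sequence is shared with other annotated genes, so their counts depend on how shared reads were assigned. The remaining genes among the 10 were Xist, Fam213b, Rragb, which encodes a GTPase of amino acid signalling, and Fggy, a carbohydrate kinase. Of the 132 calls, 6 held without each line in turn: Ddx3y, Eif2s3y, Kdm5d, Uty, Xist and, chosen after its values were seen, Eno1b. Eno1b, an enolase gene on chromosome 18 (48045335 to 48048412), fell from 182 ± 40.1 to 12.1 ± 1.98 CPM. Of its sequence, 76.4% also occurs in Eno1, which was at 0.523 ± 0.165 and 0.622 ± 0.196 CPM, so the counts of both depend on how shared reads were assigned.

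None of the transcripts of regulators tied to the study's question, the action of the antioxidant through BACH1 and glycolysis, passed the test. Protein was not measured, so these values do not show whether BACH1 or NRF2 protein differed. On simulated counts the test recovered 10 of 100 genes changed 2-fold. Bach1, a repressor of haem and antioxidant genes, was at 49.6 ± 17.3 CPM in control and 43.9 ± 9.12 CPM in NAC lines (adjusted p = 0.761). Nfe2l2, which encodes the antioxidant regulator NRF2, was at 372 ± 85.5 and 404 ± 109 CPM (adjusted p = 0.846), and its inhibitor Keap1 at 96.4 ± 8.31 and 104 ± 10.9 CPM (adjusted p = 0.713). Kras (101 ± 12.3 and 112 ± 28.4 CPM) and Trp53 (202 ± 27.95 and 233 ± 29.9 CPM) were likewise within the spread between lines, at adjusted p = 0.760 and 0.542. Hmox1, haem oxygenase, averaged 16.3 ± 9.25 and 37.3 ± 36.4 CPM (adjusted p = 0.404), NAC line 2 alone being at 91.6 CPM.

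Of the glycolysis genes and the hypoxia-inducible factor (HIF) targets, 1 passed over all genes. Hexokinase 2, Hk2, which commits glucose to metabolism, was at 231 ± 58.7 CPM in control and 461 ± 22.3 CPM in NAC lines, all NAC lines above all control lines, and missed the threshold over all genes (log2 fold change 1.00, SE 0.20, adjusted p = 0.0699). It was the 1 glycolysis gene of 19 that passed when adjusted over the list alone, and 0 of 19 passed over all genes. Of the 13027 tested genes, 2391 had an unadjusted p under 0.05. A pass over a short list alone is therefore a weaker result than a pass over all genes. Gapdh was at 3502 ± 866 and 4601 ± 152 CPM (adjusted p = 0.363), and the lactate transporter Slc16a1 at 76.6 ± 9.86 and 128 ± 27.0 CPM (adjusted p = 0.128). Pfkp, a phosphofructokinase, had a lower value, at 62.4 ± 37.9 and 30.9 ± 11.5 CPM (adjusted p = 0.337). It lies on chromosome 13, where 87.5% of the genes above a mean log2 CPM of 4 were lower in NAC lines. Eno1, 1 of the 19 genes, was at 0.523 ± 0.165 and 0.622 ± 0.196 CPM. Its counts depend on how reads shared with Eno1b were assigned. Of the Gapdh sequence, 25.1% occurs in other annotated genes, so the same limit holds for Gapdh. As a list, glycolysis and lactate export had 11 higher and 8 lower values, with a median log2 fold change of 0.09, and did not pass (camera adjusted p = 0.168). It did pass without control line 1 (adjusted p = 0.0434) or 2 (adjusted p = 0.0133), or with both summed (adjusted p = 0.0231). Only control line 3 had a list mean below the NAC lines, at -0.70 log2 units relative to the control mean. Control lines 1 and 2 (0.32 and 0.38) lay above each NAC line (0.09 to 0.16). DESeq2 called 2 of the glycolysis genes, Hk2 (adjusted p = 0.00131) and Slc16a1 (adjusted p = 0.0333), and both are in the authors' deposited table. HIF targets outside glycolysis passed as a list (17 genes, median log2 fold change 0.33, camera adjusted p = 0.00519; adjusted p = 0.626 with an estimated correlation), and not without control line 3 (adjusted p = 0.342). The list mean of control line 3 was -0.78 log2 units relative to the control mean, and that of NAC line 4 (0.29) lay below those of control lines 1 and 2 (0.30 and 0.48). P4ha2, a collagen prolyl hydroxylase, rose from 34.97 ± 5.05 to 80.8 ± 16.2 CPM (adjusted p = 0.0481). Adjusted over the list alone, P4ha2, Vegfa (234 ± 83.8 and 499 ± 90.7 CPM), Ddit4 (153 ± 59.7 and 312 ± 50.4 CPM) and Egln1 (129 ± 55.6 and 276 ± 44.6 CPM) passed.

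Among antioxidant, iron, tricarboxylic acid cycle and respiratory genes, 1 passed over all genes. Of 22 NRF2 target genes 1 changed: Nqo1, a quinone reductase, fell from 3.23 ± 0.582 to 0.159 ± 0.0611 CPM (adjusted p = 0.0133), low in both groups; the list did not pass (camera adjusted p = 0.694), and Prdx1 (542 ± 193 and 347 ± 27.4 CPM) and Me1 (263 ± 19.2 and 334 ± 52.2 CPM) went opposite ways without passing. None of 15 genes of haem and iron handling passed, over all genes or adjusted over the list alone (camera adjusted p = 0.712), with Mafg at 46.4 ± 8.75 and 75.8 ± 9.49 CPM and the ferritin gene Ftl1 at 2997 ± 778 and 1801 ± 252 CPM. The 24 glutathione and peroxide enzymes held 18 genes with lower values and 0 past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.110). Catalase, Cat, was at 180 ± 90.2 and 88.1 ± 15.1 CPM, and Nnt, the mitochondrial transhydrogenase, at 129 ± 33.6 and 84.4 ± 12.7 CPM (adjusted p = 0.194). In the tricarboxylic acid cycle 0 of 21 genes passed in either way (camera adjusted p = 0.269). Sdha, which also lies on chromosome 13, was at 282 ± 57.0 and 184 ± 20.9 CPM. Genes of the nuclear-encoded respiratory chain passed as a list with lower values (37 genes, 28 of them lower, median log2 fold change -0.24, camera adjusted p = 0.0302; adjusted p = 0.781 with an estimated correlation). No member passed over all genes; Uqcrb, of complex III, at 66.8 ± 3.44 and 36.1 ± 5.42 CPM, was the 1 that passed adjusted over the list alone. Uqcrb, Cox7c and Uqcrfs1 lie on chromosome 13, and with members on chromosomes 13 and X left out the list no longer passed (adjusted p = 0.0754), though the median over the 33 genes left stayed at -0.24. The 13 mitochondrially encoded genes are absent from the count table. The nuclear-encoded list also did not pass without control line 2 (adjusted p = 0.994, in the other direction), NAC line 1 (0.0544) or NAC line 2 (0.185), with control lines 1 and 2 summed (0.0758) or after the GC content and length correction (0.388). Control line 2 alone had a list mean above the control mean, by 0.34 log2 units, and control lines 1 and 3, at -0.15 and -0.19, lay among the NAC lines.

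Cholesterol synthesis was the list with the lowest p after the 22 genes were tested together: 21 had higher values in NAC lines, with a median log2 fold change of 0.75 (camera adjusted p = 2.18e-09; adjusted p = 0.565 with an estimated correlation). Ldlr, the low density lipoprotein receptor (chromosome 9, 21723483 to 21749919), rose from 204 ± 9.65 to 418 ± 51.2 CPM (log2 fold change 1.03, SE 0.16, adjusted p = 0.0314), and Hsd17b7, a sterol reductase, from 16.5 ± 2.13 to 37.8 ± 6.88 CPM (adjusted p = 0.0415). Sqle, squalene epoxidase, was at 80.9 ± 9.12 and 210 ± 62.1 CPM (adjusted p = 0.0537) and Fdps at 169 ± 39.0 and 365 ± 71.0 CPM (adjusted p = 0.0733). Adjusted over the list alone 11 genes passed, all higher, and the camera call held without each line in turn (highest adjusted p = 1.46e-05). Leaving out a line keeps the same groups, so it does not test chance. Of the 35 splits of the lines, 2, the real one included, moved the list's median as far. The other split set mTN11, mTN12 and mTN13 against the remaining lines, which is close to the real grouping. As many as 10 lists passed in 5 of the 35 splits, the real one included. A camera pass of any list here thus does not exclude chance.

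Targets of p53 also passed as a list in NAC lines, 15 of 16 with higher values (median log2 fold change 0.74, camera adjusted p = 0.000128; adjusted p = 0.565 with an estimated correlation). None passed over all genes, and Bbc3, a trigger of apoptosis (55.8 ± 25.1 and 175 ± 42.7 CPM), and Aen (41.2 ± 12.2 and 82.1 ± 17.9 CPM) passed adjusted over the list alone. The amino acid stress genes downstream of ATF4 had 17 of 20 values higher and passed as a list (median log2 fold change 0.48, camera adjusted p = 0.00519; adjusted p = 0.626 with an estimated correlation), with no member past the threshold over all genes or over the list alone; Aldh1l2 was at 26.2 ± 10.2 and 73.5 ± 35.7 CPM, with NAC line 4 at 21.2 CPM. Without control line 1 the ATF4 list did not pass (adjusted p = 0.119), and NAC line 4 did not share the higher values, with a list mean of -0.02 log2 units relative to the control mean. Endoplasmic reticulum chaperones had a median log2 fold change of -0.00 over 16 genes and 0 calls of either kind (camera adjusted p = 0.595), but passed without control line 3, where Pdia3 was at 1765 CPM against 626 and 705 CPM in control lines 1 and 2 (adjusted p = 0.00619). The proliferation list passed with 20 of 24 values lower (median log2 fold change -0.33, camera adjusted p = 0.0247; adjusted p = 0.781 with an estimated correlation), and 0 members passed over all genes or over the list alone. Kif11, a spindle motor, was at 68.0 ± 23.1 and 37.4 ± 12.1 CPM. NAC line 4 did not share the lower values of the proliferation list, with a mean of 0.22 log2 units above the control mean. Control line 3 did share them, at -0.46, below NAC line 2 (-0.29). The list did not pass without control line 1, control line 2, NAC line 1 or NAC line 3 (highest adjusted p = 0.237), with control lines 1 and 2 summed (0.13995) or after the GC content and length correction (0.0577). The RAS-MAPK output list did not pass (17 genes, camera adjusted p = 0.0845), except without NAC line 1 (adjusted p = 0.0296) or NAC line 3 (adjusted p = 0.0353); Phlda1, at 198 ± 35.3 and 631 ± 324 CPM, passed adjusted over the list alone. The Wnt and Hippo target genes passed with 10 of 10 values higher (median log2 fold change 0.68, camera adjusted p = 0.0302; adjusted p = 0.565 with an estimated correlation), 0 over all genes and 2 over the list alone: Znrf3 (16.8 ± 5.27 and 38.0 ± 9.10 CPM) and Ajuba (155 ± 16.9 and 267 ± 60.5 CPM). That list did not pass without control line 3 (adjusted p = 0.0619), NAC line 2 (0.193) or NAC line 4 (0.0698), or after the GC content and length correction (0.0577). NAC line 3 did not share the higher values, with a list mean of -0.16 log2 units relative to the control mean, against 1.39 in NAC line 2.

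**Figure D3:**
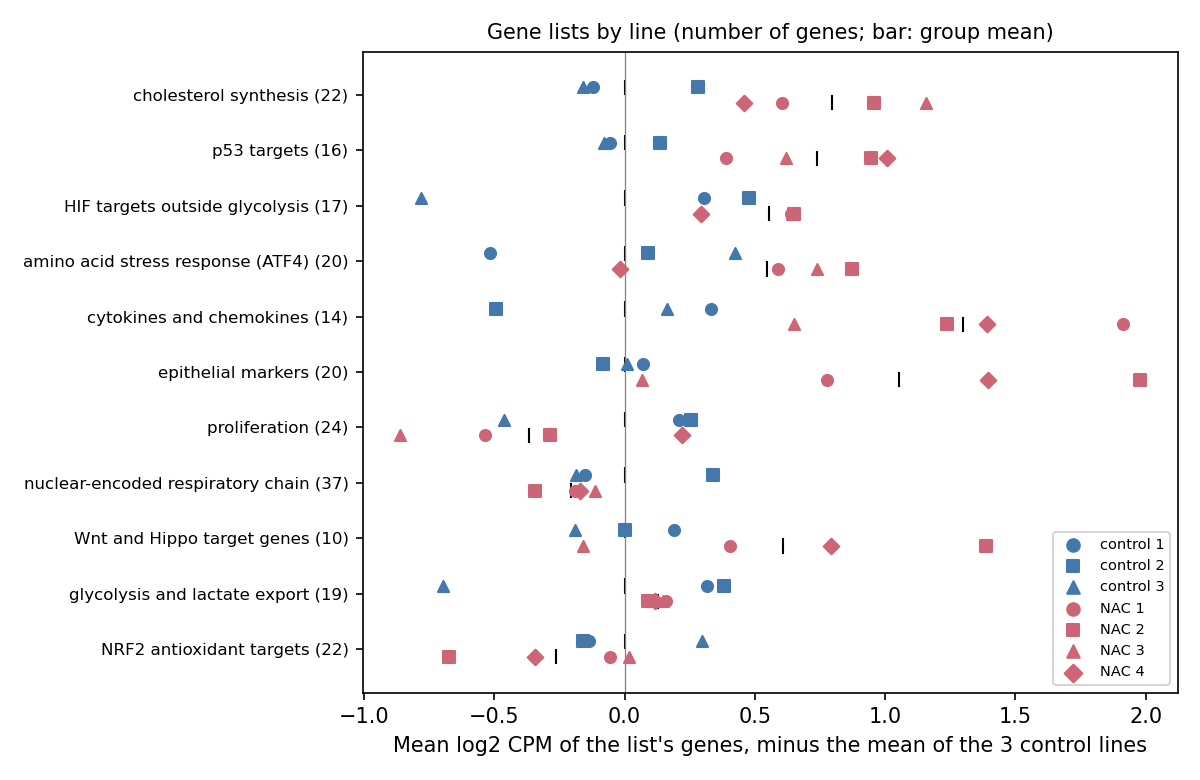
Mean log2 CPM of each list's genes in each line, relative to the mean of the 3 control lines; symbols mark lines 1 to 4 and bars are group means. The lists that passed the camera test are ordered by p, the sex-linked genes left out, followed by glycolysis and NRF2 targets; for cholesterol synthesis the NAC lines lie between 0.46 and 1.16 and the control lines between -0.16 and 0.28.

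The epithelial markers had a median log2 fold change of 0.78 and 15 of 20 values higher (camera adjusted p = 0.0247; adjusted p = 0.626 with an estimated correlation), with 0 past the threshold over all genes. Epcam, an epithelial adhesion molecule, was at 7.70 ± 3.94 and 67.3 ± 48.1 CPM (adjusted p = 0.0855); the 1 gene that passed adjusted over the list alone was Epcam. Esrp1, a splicing regulator of epithelia, was at 92.2 CPM in NAC line 2 and at 1.68 CPM or below in the other lines. The list did not pass without control line 2 (adjusted p = 0.1196), control line 3 (0.0525) or NAC line 4 (0.149), with control lines 1 and 2 summed (0.0697) or after the GC content and length correction (0.0607). NAC line 3 did not share the higher values: its list mean was 0.07 log2 units above the control mean, as was that of control line 1 (0.07), against 0.78, 1.98 and 1.39 in NAC lines 1, 2 and 4. Mesenchymal markers and factors of the epithelial-mesenchymal transition did not pass as a list (17 genes, camera adjusted p = 0.712), and their median (0.08) and mean (-0.51) differed in sign. Acta2 was the 1 call, and Zeb1 (52.9 ± 11.6 and 28.03 ± 5.49 CPM) also passed adjusted over the list alone. Of 16 genes of alveolar type 2 cells and lung identity, 7 were expressed enough to be tested and 0 passed in either way (camera adjusted p = 0.648); Sftpc, the surfactant protein C gene, stayed at or below 0.0251 CPM in every line. Gastric and endodermal genes did not pass as a list (16 genes, camera adjusted p = 0.824). Tff2, a trefoil peptide of gastric mucosa, was at 174, 177 and 122 CPM in NAC lines 1, 3 and 4, 0.146 CPM in NAC line 2 and 1.70 ± 0.952 CPM in control lines. Adjusted over the list alone, Tff1 and Tff2 passed higher and Gkn1 lower, and none of these genes passed over all genes. Gkn1 was at 0.570 ± 0.334 and 0.0375 ± 0.0238 CPM, near the floor in NAC lines.

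Of the cytokine, interferon, class I and matrix genes, a few passed. Cytokines and chemokines had 13 of 14 values higher (median log2 fold change 0.97, camera adjusted p = 0.00519; adjusted p = 0.565 with an estimated correlation). Il1a was the 1 call over all genes, and Csf3 (0.492 ± 0.0849 and 5.39 ± 4.63 CPM) and Cxcl3 (1.08 ± 0.929 and 10.1 ± 6.38 CPM) also passed adjusted over the list alone. The list did not pass without control line 2 (adjusted p = 0.0735). Genes of the interferon response did not pass (19 genes, 15 with lower values, median log2 fold change -0.55, camera adjusted p = 0.0845), except without control line 3 (0.0407) or NAC line 1 (0.0238). Mx1, an antiviral GTPase, was the 1 call over all genes and over the list alone, higher at 1.24 ± 0.408 CPM from 3 control counts (ratio 51.5, counting interval 17.4 to 252). Class I antigen presentation did not pass (13 genes, camera adjusted p = 0.648), with H2-K1, at 171 ± 20.5 and 302 ± 59.7 CPM, past the threshold adjusted over the list alone. Matrix, integrin and protease genes did not pass (25 genes, camera adjusted p = 0.896; 0 over all genes). Over the list alone Plaur, the urokinase receptor (286 ± 58.2 and 610 ± 101 CPM), and Itgb6 passed higher and Mmp14, a membrane metalloprotease (305 ± 37.4 and 165 ± 26.3 CPM), passed lower.

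Most markers of fibroblasts, leukocytes, endothelium and mesothelium stayed below 1 CPM in every line. Of 14 fibroblast genes, 11 stayed below 1 CPM in every line, Col1a2 and Dcn among them, and 1 of the 4 tested genes changed: Fbln1, a matrix glycoprotein, fell from 34.3 ± 2.84 to 7.31 ± 3.42 CPM (adjusted p = 0.0410). Col5a1, a fibrillar collagen gene, was at 12.7 ± 4.47 and 18.6 ± 11.7 CPM (adjusted p = 0.593). Fbln1 and Col1a1 passed adjusted over the list alone, in opposite directions. Col1a1 was low, at 0.616 ± 0.252 and 1.52 ± 0.381 CPM, and did not pass over all genes (adjusted p = 0.196). For leukocytes, 15 of 16 genes stayed below 1 CPM in every line and 1 was tested; for endothelium, 7 of 10 did and 3 were tested; none changed, over all genes or over the list alone. Mesothelial genes other than Msln stayed below 1 CPM; Msln, which lung tumour cells can also express, was at 719 ± 170 and 1273 ± 229 CPM, and passed adjusted over the list alone but not over all genes (adjusted p = 0.125). Airway club and ciliated genes (5 tested, camera adjusted p = 0.471; 0 calls of either kind) and alveolar type 1 genes (7 tested, camera adjusted p = 0.824; 0 over all genes) did not pass, and some of these were abundant: Tuba1a, a tubulin gene, was at 271 ± 142 and 135 ± 111 CPM and Cav1, encoding caveolin, at 151 ± 46.1 and 232 ± 131 CPM. Over the list alone Aqp5, a water channel, at 1.997 ± 1.26 and 85.1 ± 69.4 CPM, and Akap5 passed in opposite directions.

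Expression also differed by chromosome. The median log2 fold change of genes on chromosome 13 was -0.44 over 271 genes above a mean log2 CPM of 4, and 87.5% of them were lower in NAC lines. NAC line 3 was farthest from the mean of all lines, at -0.47 log2 units, against -0.08, -0.08 and -0.14 in NAC lines 1, 2 and 4. Called genes lay on chromosome 13 more often than elsewhere, with 9 lower and 1 higher among 506 tested. For the lower calls the odds ratio was 4.30 (Fisher's exact test, p = 0.000576, adjusted p = 0.0230 over 40 tests of 20 chromosomes in both directions). That test takes genes as independent, which genes that shift together along a chromosome are not. On X the median was -0.28, with 7 calls, all lower (adjusted p = 0.0502). On chromosomes 1, 7, 10, 11, 12 and 15 each NAC line lay above each control line, by less: the largest median log2 fold change was 0.17, on chromosome 11, and 30.6% of its genes were lower. Some shifts did not follow the groups. Control lines 1 and 2 shared higher medians on chromosomes 14 (0.23 and 0.25 log2 units above the mean of all lines) and 19 (0.27 and 0.27), where control line 3 was at -0.11 and -0.27. The medians of chromosomes 2 and 17 were 0.41 and 0.38 above in control line 3, that of chromosome 5 was 0.34 above in NAC line 2 and that of X was 0.62 below in NAC line 4 (-0.62).

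**Figure D4:**
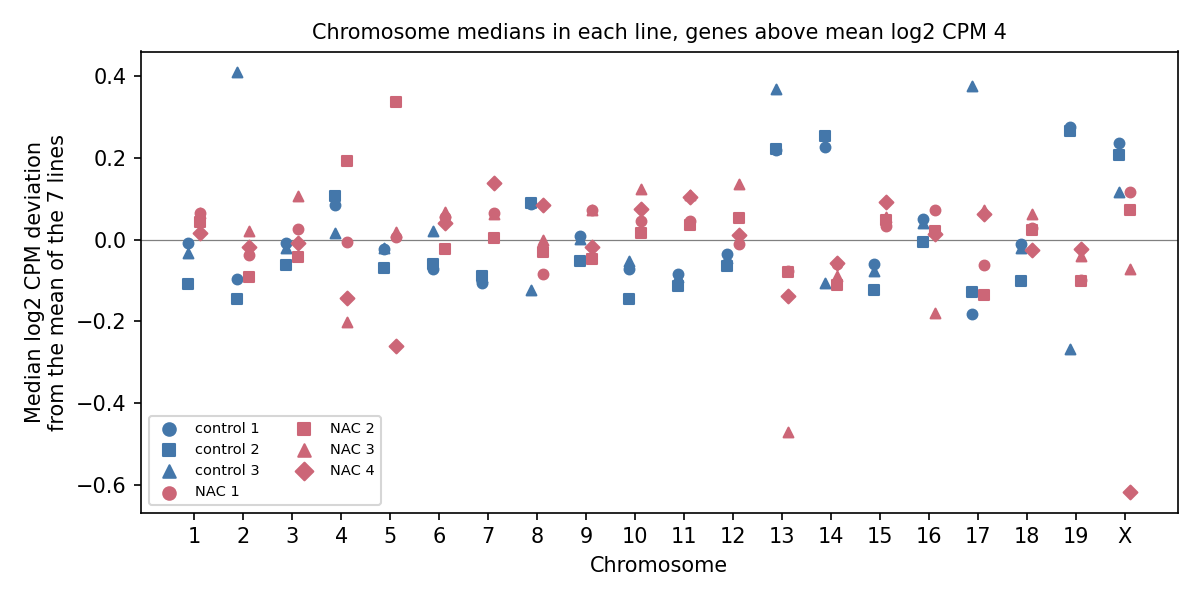
Median deviation of log2 CPM from the mean of the 7 lines, for the genes of each chromosome with a mean log2 CPM above 4; symbols mark lines 1 to 4 of a group. On chromosome 13 each control line lies at 0.22 or above and each NAC line at -0.08 or below.

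The authors' deposited table lists 1025 genes, with adjusted p up to 0.0499, 552 with a positive and 473 with a negative log2 fold change. The table does not state its direction. Of its genes 1000 were tested here, and the sign matched higher in NAC lines for all 1000. It holds 129 of the 132 genes called here; the other 3 are Acta2, Bgn and Adamts2, the last chosen after its values were seen. DESeq2, rerun on the counts, called 1087 genes, of which 1020 are in the authors' deposited table with the same sign. In the authors' deposited table Hk2 has a log2 fold change of 0.96 (SE as deposited 0.23, adjusted p = 0.00132) and P4ha2 of 1.15 (adjusted p = 0.00012), Nqo1 of -3.57 and Ddx3y of 7.39, while Gapdh, Bach1 and Hmox1 are not among its genes. It lists 8 of the 22 cholesterol synthesis genes, all higher. Its log2 fold changes for Hk2, P4ha2, Nqo1 and Ddx3y are smaller in size than those of DESeq2 rerun here (1.00, 1.22, -4.34 and 8.61). For Peg12 it has -4.77, against -9.48 in the rerun. The deposited values are thus not on the same scale as those here, and the cause was not tested.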

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

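The tests of Y chromosome loss and of the sex of the source animals, the splits for chromosome 13 and for cholesterol synthesis, the splits with control lines 1 and 2 as 1 sample, and the use of the SD in the test of escape genes were chosen after the results were seen. Among 108 gene values and list scores of the 4 NAC lines, 10 had 1 line far from the other 3, where chance gives about 1 in 20 groups, or 5.4, and 6 of the 10 were in NAC line 2. Of these 10, 3 rest on at most 3 counts in each line, too few to set a line apart, 2 of them in NAC line 2: Gkn1 (0.0730 CPM, others 0.0230 to 0.0276) and Rragb (0.0486 CPM, others 0) in NAC line 2, and Fam213b (0.0552 CPM, others 0.0230 to 0.0263) in NAC line 4. NAC line 2 was high in Esrp1 (92.2 CPM, others 0.386 to 1.68) and Hmox1 (91.6 CPM, others 15.5 to 23.5). It was low in Nfe2l2 (240.3 CPM, others 452 to 471) and in the gastric and endodermal list score (-1.80, others 0.51 to 0.71). NAC line 1 was high in Cox7c (96.8 CPM, others 76.8 to 78.0) and Cxcl3 (19.6 CPM, others 5.98 to 7.75). NAC line 4 was low in the HIF list score (0.29, others 0.64 to 0.65).

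Sex-linked transcripts parted the lines exactly by group. Loss of the Y chromosome from male control lines was argued against, since the lowest control Xist was 275 times the highest NAC Xist. The Xist of each control line and the Y transcripts of each NAC line are those of female and of male cells. A test on 5 genes known to escape X inactivation could not decide on female origin of the control lines and male origin of the NAC lines. The median of these 5 genes was -0.14 relative to all tested X genes, with 3 below and 2 above and an SD of 0.33. Of the 35 splits only the real one called as many genes (132, highest other 3), which excludes chance only if all 7 lines are independent: with control lines 1 and 2 as 1 sample, the 15 splits are too few for a share under 0.05 (real 7, highest other 0). For the 121 autosomal calls, NAC given to the mice and sex of the source animals cannot be told apart, since no group holds lines of both kinds.

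Chromosome 13 genes were lower in NAC lines. Of the 35 splits, 1, the real one, moved an autosome's median as far (0.47, highest other 0.42). That highest other split set mTN12, mTN13 and mTN14 against the remaining lines, which is close to the real grouping. With control lines 1 and 2 as 1 sample, however, the 15 splits are too few for a share under 0.05 (0.50, highest other 0.44). A GC content and length trend as the whole cause was argued against, as the median difference was -0.39 after the correction and -0.47 before. A difference in copy number of the whole chromosome may account for it, since each of 5 segments was lower, the highest at -0.41; DNA was not measured. NAC and sex of the source animals were not tested as its origin.

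Cholesterol synthesis genes were higher in NAC lines, with a median difference of 0.79. Chance could not be excluded: 2 of 35 splits moved the median as far, the highest other at 0.82. That other split set mTN11, mTN12 and mTN13 against the remaining lines, which is close to the real grouping. For the 10 lists past the threshold 5 of 35 splits gave as many, the highest other being 12 and the lowest 2. A GC content and length trend was argued against (0.81 after correction), and so was the copy number of the 14 chromosomes that carry the 22 members (0.99 after each chromosome's median was subtracted). An effect of NAC, sex of the source animals and differences between single lines stay open.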

How the results depend on the processing

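Autosomal genes alone, chromosomes X, Y and 13 left out, the GC content and length correction, control lines 1 and 2 summed and the bias-adjusted quasi-likelihood method were chosen after results were seen. Leaving out 1 line gave 4 to 109 higher, 2 to 152 lower and 6 to 261 changed genes, and separation p from 0.0667 to 0.2, in designs that cannot reach 0.05. DESeq2 called 579 higher and 508 lower genes (1087), with 1020 in the authors' table. The replicate block called 1112 higher and 1022 lower genes (2134); it pairs mTC11 with mTN11 and mTC14 with mTN14 by the number in their names alone, has 1 residual degree of freedom, and the deviations of these pairs correlated at 0.131 and -0.00786 across genes. Summing control lines 1 and 2 gave 5 higher and 2 lower genes (7), with fewer samples, and the bias-adjusted method 113 and 127 (240). Of 10 lists past the threshold, 0 passed with an estimated correlation. With fry 1 passed, the sex-linked genes. The next lowest fry adjusted p was 0.129, for cholesterol synthesis, p53 targets, and cytokines and chemokines. With the GC content and length correction 6 passed (lost: respiratory chain, epithelial, proliferation, Wnt and Hippo). The respiratory chain list reversed without control replicate 2 (adjusted p = 0.994, the highest of the leave-outs, the lowest being 0.00346). Except for the smaller designs, the cause was not tested. Of 2693 alternative values of named genes, 2460 stayed on the same side of the threshold, 120 lost the call and 113 gained one. A change of sign was counted only where 1 of the 2 fits called the gene, and 0 such changes were found. Genes without a call could change sign, as Bach1 did (log2 fold change from -0.39 to 0.10 over the leave-outs). Of 350 list values, 300 stayed on the same side of the threshold, 41 lost the call, 8 gained one and 1 changed direction with a call. Depth limited ratios for genes with at most 3 counts in a group.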

Other observations

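The test of control lines 1 and 2 was chosen after the result was seen, as were the genes of the protocadherin gamma family. NAC line 2 stood apart from the other NAC lines, at distances of 79.7 to 97.1, against 43.3 to 47.9 among lines 1, 3 and 4. Of 12 tested protocadherin gamma genes, clustered on chromosome 18, 8 had lower values in NAC lines and 2 were called, both lower, with a median log2 fold change of -0.12. Pcdhgb1 was at 0.405 ± 0.681 CPM (SD, n = 3) and 6.27 ± 1.44 CPM (SD, n = 4), and Pcdhgc3 at 45.1 ± 3.83 and 41.0 ± 6.45 CPM; neither was called.

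Control lines 1 and 2 may share a clone or tumour of origin. Their autosome medians differed by at most 0.102 log2 units, the smallest such value of 21 pairs of lines, the next being 0.266. Over all genes the pair was not the most alike: its counts gave a chi-square per degree of freedom of 158.7, against 63.8 for NAC lines 1 and 3, 111.0 for NAC lines 1 and 4, 143.0 for NAC lines 3 and 4 and 151.7 for control line 1 and NAC line 1. All are far above sampling error, so no 2 of these libraries are 1 library entered again. Separate tumours with alike chromosome content stay open.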
